A study of Mus musculus with 4 samples.

How the data were processed

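Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on colon tissue of wild-type mice given dextran sulfate sodium (DSS), an agent that injures the colonic epithelium and is used to model colitis. The 4 libraries comprise 2 ChIP libraries and 2 input libraries (sheared chromatin without immunoprecipitation). Per the labels' protocols, tissue was cross-linked with formaldehyde, chromatin was sonicated, and libraries were sequenced as read pairs on an Illumina instrument. The series title names the ETS-family transcription factor ELF-1, while the labels do not name the antibody. Grouping was taken from the sample titles. Nothing in the labels says whether replicates 1 and 2 came from separate animals.

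The file used here is a single deposited list of peak intervals for the whole series, with 4 columns holding a chromosome, a start, an end and a running peak name. The deposited list gives no score, height, fold enrichment, p-value, summit or gene assignment, and no column belongs to a single library. Whether the authors called peaks on pooled libraries or merged them afterwards is not given in the sources used here, and neither are the aligner, the peak caller and its threshold. The submitters' processing notes name Trimmomatic 0.36 and SAMtools 1.3.1, and list GRCm38 and GRCm39 without saying which applies to the list. The last peaks on chromosomes 1, 7 and X lie 111206, 346109 and 1347911 bp beyond the ends of those chromosomes in GRCm39, so the coordinates were taken as GRCm38. Starts were read as BED starts, counted from 0, and are printed counted from 1. Sequencing depth is unknown, so no statement about read counts was possible. The number of peaks sets the precision, and intervals on shares of peaks are 95% Wilson intervals that cover counting error only.

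Peaks were compared with the spans of 21883 protein-coding genes on the 21 assembled nuclear chromosomes in the RefSeq annotation of GRCm38.p6. The gene table used here has the first and last base of each gene but no strand, exons or internal transcription start sites. Distance to a promoter was therefore replaced by distance from the peak midpoint to the nearer end of a gene, which may be its 5′ or its 3′ end, and exon, intron and UTR positions were not assigned. Observed counts were set against 1000 random placements of the same number of peaks with the same widths within the same chromosome, between the first and last gene or peak of that chromosome. Assembly gaps could not be left out. They hold no genes, so the random lists, if anything, lie slightly too far from genes. This is a permutation test of peak positions. Its empirical p-values are one-sided for more peaks, as planned, with two-sided values added. The smallest p that 1000 placements can give is 0.000999. Two-sided values for 9 location classes (5 distances from a gene end and 4 kinds of gene span) were adjusted together by the Benjamini-Hochberg method.

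For 19 gene lists, members with a peak within 1 kb of a gene end were compared with all other protein-coding genes by Fisher's exact test, one-sided for more, with Benjamini-Hochberg adjustment over the lists. The lists covered epithelial junctions, goblet cells and mucus, stem cells and Wnt signalling, colonocytes, cell cycle, cell death, inflammatory signalling, antimicrobial defence, the ETS family, lymphocytes, myeloid cells, endothelium with fibroblasts and muscle, autophagy and lysosome, DNA repair, the cytosolic ribosome, the mitochondrial ribosome, the respiratory chain, the proteasome and, as a negative control, olfactory receptors. Peak density per chromosome was compared with the other autosomes by an exact two-sided binomial test adjusted over 21 chromosomes.

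The gene lists, a test of peaks and a test of the lists at 1 kb, and the rule for named genes were fixed before the data were examined. The tests were planned for distance from a transcription start site. Gene ends took the place of start sites only after the data were seen, because the gene table used here has no strand. The tests as run at gene ends were therefore not fixed beforehand. The two-sided tests, the distances of 100 bp and 10 kb, gene spans, nearest genes, gene bodies, peak width as the measure in place of score (its 3 kb distance was planned), density by chromosome and the comparisons of chromosome 16 were added after the data were seen. The rule names Elf1, the 15 highest peaks at promoters, the 10 highest of the rest, and up to 4 members per gene list. The list of peaks has no measure of height, so the peaks tie and the rule's tie-break, genomic position, decided which peaks are named. A few genes that the rule would name are not reported here. Other genes named below as near a peak were chosen after their positions were seen, as is said beside them. Planned tests for the ETS motif were not run because no genome sequence was used here, and the planned test of peak score by location was replaced by peak width. Alternatives covered the distance from a gene end, gene assignment, wider peaks, shifted lists and sets of chromosomes.

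The placement test was tested on simulated lists of 2377 peaks, placed at random before any were planted. Of 100 lists with no planted peaks, 5% were called. Planting 1% of the peaks at protein-coding gene ends led to a call in 69% of 100 lists, and planting 2% led to a call in 100% of them. For the epithelial junction list, planting peaks at 2 of the 21 members led to a call in 53% of 100 lists and planting at 3 members in 100%. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.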

Results

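ChIP-seq of DSS-treated wild-type mouse colon was represented by 2 ChIP and 2 input libraries and by 1 list of 2391 peaks. Of these peaks, 2377 lay on the 21 assembled nuclear chromosomes and 14 on unplaced sequences. Peaks were narrow, with a median width of 249 bp, a 25th percentile of 228 bp and a range of 215 to 743 bp. Together they covered 651 kb. The design contains no untreated or mutant tissue, so the comparisons are between peaks and the rest of the genome, and no value has a replicate error.

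The first question was whether genes of intestinal function lay at the peaks. The gene of the factor named in the series title, Elf1 (chromosome 14, 79481174 to 79582491), had no peak inside it or within 1 kb, and the nearest peak lay 213 kb away at 79795743 to 79795982. Among goblet cell and mucus genes, 1 of 16 had a peak at a gene end: Zg16, which encodes a lectin of goblet cell granules, held a peak at 127051005 to 127051260 on chromosome 7, with its midpoint inside the gene and 976 bp from one end. Tfeb, a transcription factor that activates lysosomal and autophagy genes, held a peak at 47791515 to 47791810 on chromosome 17, inside the gene and 754 bp from one end. Another peak lay outside Cd2, an adhesion receptor of T cells, at 101288094 to 101288466 on chromosome 3, 341 bp beyond one end of the gene. Whether these are 5′ or 3′ ends was not known.

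Peaks deeper inside listed genes were also few, as they were in random placements. For genes with a peak inside or within 1 kb, random means were 1.39 in the stem cell and Wnt list. The random mean was 0.96 in the autophagy and lysosome list. In the list of stem cell and Wnt genes, 2 of 17 members held a peak: Lgr5, a receptor that marks intestinal stem cells (chromosome 10, 115538635 to 115538915, 49.0 kb from the nearer gene end), and Znrf3, a ubiquitin ligase that removes Wnt receptors from the cell surface (chromosome 11, 5395075 to 5395370, 49.6 kb from the nearer end). Gabarapl1, an autophagosome protein, held a peak at 129537317 to 129537565 on chromosome 6, so that 2 of the 20 autophagy and lysosome genes had a peak inside or within 1 kb. Itgb2, the shared β chain of leukocyte integrins, was the single member among 13 myeloid genes (chromosome 10, 77543163 to 77543464). Chek2, a DNA damage checkpoint kinase, held 2 peaks on chromosome 5, at 110842774 to 110843016 and at 110859215 to 110859448, and was the single gene among 24 of DNA repair. Ndufs4, a subunit of respiratory complex I, was the single gene among 92 of the respiratory chain (chromosome 13, 114351544 to 114351761).

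In 11 of the 19 lists no member had a peak inside it or within 1 kb. These were the lists for epithelial junctions (21 genes, among them the tight junction genes Tjp1 and Ocln and the adherens junction gene Cdh1), colonocytes (18), cell cycle (22), cell death (20), inflammatory signalling (22), antimicrobial defence (13), the ETS family (26), endothelium with fibroblasts and muscle (16), the cytosolic ribosome (81), the mitochondrial ribosome (78) and the proteasome (40). Taking 3 counts as the limit that a count of 0 allows, 0 of 21 junction genes allows a share of up to 14.3%, and 0 of 81 cytosolic ribosome genes a share of up to 3.70%. Random placements gave means of only 0.28 (antimicrobial defence) to 1.24 members (the ETS family) in these 11 lists. A count of 0 is the lowest possible, and its one-sided p for fewer was 0.248 or higher (permutation of positions). The test therefore could not have called a shortage in any of these lists. Of the 1110 olfactory receptor genes, the negative control, 3 had a peak, against a random mean of 4.05. These were Olfr122 and Olfr1431 at a gene end and Olfr145 inside.

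No list held more genes with a peak at a gene end than other protein-coding genes did after adjustment (Fisher's exact test, 0 of 19 lists, lowest adjusted p = 0.333). Before adjustment, 2 lists had an exact p under 0.05, namely goblet cells and mucus (1 gene against 0.043 expected, p = 0.042) and lymphocytes (1 gene against 0.049 expected, p = 0.047), each through a single gene. Across the 18 lists other than olfactory receptors, 9 of 556 genes had a peak inside or within 1 kb, against a mean of 13.1 in random placements (central 95% of placements 6.98 to 20, permutation of positions, one-sided p = 0.905 for more). The simulations called the junction list in 53% of lists when 2 members were planted, so a gain of 1 or 2 genes in a list of that size was not reliably detectable.

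**Figure D1:**
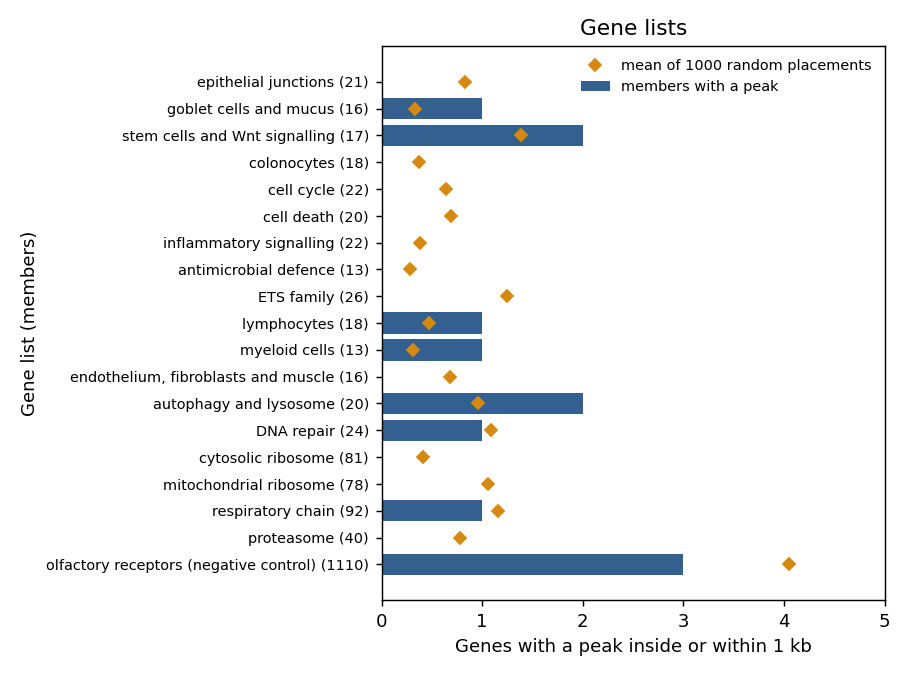
Number of genes in each list (members in parentheses) with a peak inside the gene or within 1 kb, as bars from 0, against the mean of 1000 random placements of the same peaks, as diamonds. Bars are absent for 11 lists, and none of the others exceeds the random mean by an adjusted test.

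When each peak was assigned to its nearest protein-coding gene at any distance, the stem cell and Wnt list had 6 of 17 members: Lgr5, Znrf3, Cd44, Sox9, Olfm4 and Myc, the last 2 of them outside the rule and named after their positions were seen. Fisher's exact test called this list (1.43 expected, adjusted p = 0.037), but random placement, which takes account of the wide spaces around these genes, gave a mean of 4.46 members and an adjusted p of 0.984. The Sox9 peak lay 405 kb and the Myc peak 302 kb from the gene, and the nearest of the 3 peaks assigned to Olfm4, a stem cell marker, lay 9.02 kb away. Other nearest-gene assignments included Cldn23, a claudin (98.7 kb), Klf5, a transcription factor of proliferating crypt cells (267 kb), Mki67, a proliferation marker (3 peaks, the closest at 13.7 kb), Bcl2, an inhibitor of apoptosis (32.5 kb), Tlr4, the lipopolysaccharide receptor (326 kb), and Reg3b, an antimicrobial lectin (126 kb). The lists of these genes each had 1 such member, against random means from 0.99 (cell death) to 2.17 (inflammatory signalling). All 19 lists had at least 1 nearest gene, and the placement test called none of the lists. Of the ETS family, Erg (22.5 kb), Ets1 (32.1 kb) and Etv1 (343 kb) were nearest genes, 3 of 26 members against a random mean of 3.03. Tyrobp, a signalling adaptor of myeloid cells, lay 4.26 kb from a peak, and Col1a2, a collagen gene of fibroblasts, lay 187 kb from one. The remaining nearest genes in the lists were Rps29 (599 kb), Mrpl46 (82.2 kb), Ndufa10 (25.9 kb), Psmb7 (6.29 kb), Psmd7 (16.3 kb) and, among the first 4 olfactory receptors, Olfr228 (9.70 kb).

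The second question was where in the genome the peaks lay. Peaks were not more frequent at gene ends than random placements were. Within 1 kb of a protein-coding gene end there were 58 of 2377 peaks (2.44%, 95% interval 1.89 to 3.14%), against a random mean of 72.0 peaks (3.03%), a ratio of 0.81 (permutation of positions, one-sided p = 0.965 for more, two-sided p = 0.096, adjusted p = 0.173). Within 3 kb there were 149 peaks against 194 at random, a ratio of 0.77 that passed the two-sided permutation test, with fewer peaks than at random (adjusted p = 0.036), and within 10 kb there were 452 against 499 (ratio 0.91, adjusted p = 0.045). Inside protein-coding genes lay 891 peaks (37.5%, interval 35.6 to 39.4%) against 942 at random (adjusted p = 0.108), and inside lncRNA genes 219 against 203 (adjusted p = 0.290, both by the same permutation test). Because the gene ends pool 5′ and 3′ ends, the share of peaks within 1 kb of the annotated 5′ end of a protein-coding gene cannot exceed the 2.44% given for both.

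**Figure D2:**
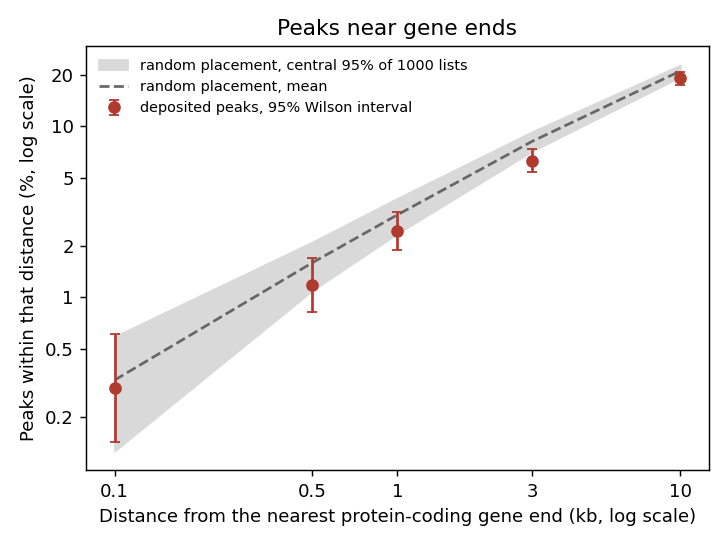
Share of the 2377 peaks (points, with 95% Wilson intervals) whose midpoint lies within 0.1, 0.5, 1, 3 or 10 kb of a protein-coding gene end, both axes on log scales, with the mean (dashed) and central 95% (grey) of 1000 random placements. The point at 1 kb (2.44%) lies inside the grey band, and the points at 3 and 10 kb lie below it.

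The 58 peaks near a gene end belonged to 59 genes, since 1 peak lay between Rhog, which encodes a small GTPase, and Pgap2 on chromosome 7 at 102238682 to 102238919, a pair singled out after its position was seen. The first 15 by position included those at Slc41a1, a magnesium transporter gene, and BC034090 on chromosome 1, Cwc22, a splicing factor gene, Svs5, a seminal vesicle protein gene, and Spata25 on chromosome 2, and Cd2 and Elapor1 on chromosome 3. They also included Mup2, a major urinary protein gene, and Kank4 on chromosome 4, and Gm9758 and Medag on chromosome 5. On chromosome 6 they lay at Gm40363 and Cd163, the haptoglobin-hemoglobin receptor gene of macrophages. Distances among those named ran from 92 bp at Kank4 to 985 bp at Slc41a1. The midpoint lay inside the gene in 33 of the 59 gene and peak pairs and outside it in 26. The first 10 other peaks by position lay on chromosome 1, inside Xkr4, St18, Sntg1, Cspp1 and Cpa6, and outside but nearest to Xkr4 (97243 bp), Sox17 (4743 bp), Oprk1 (154058 bp), Pcmtd1 (95779 bp) and Prex2 (53977 bp). Genes at ends chosen after their positions were seen included Ccdc80 on chromosome 16 (20 bp), Tmem45a2 on chromosome 16 (31 bp), Rack1, a ribosome-bound scaffold gene on chromosome 11 (534 bp), and Kitl, the gene for the Kit ligand on chromosome 10 (829 bp).

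Chromosome 16, tested after its peaks were seen, differed from the others in this respect. It had 10 of its 90 peaks (11.1%) within 1 kb of a gene end, against 48 of 2287 peaks (2.10%) elsewhere (Fisher's exact test, two-sided p = 4.3e-05, 9.0e-04 after correction for 21 chromosomes). Random placement gave a mean of 2.13 such peaks on chromosome 16 and an adjusted p of 0.042 over 21 chromosomes, and within 3 kb the adjusted p was 0.126. The 10 genes, listed after their positions were seen, were Alg1, Fetub, Cpn2, Ccdc80, Nectin3, Tmem45a2, Krtap15, Gm33084, Olig1 and Kcnj6. Without chromosome 16 the other peaks near gene ends numbered 48 against 69.9 at random (ratio 0.69). Since chromosome 16 was left out for its excess, this ratio is lower by construction.

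Peak density was lower on the sex chromosomes than on the autosomes. Whether the autosomes differ among themselves as a set was not tested. Autosomes held 2301 peaks, 0.94 per Mb. Chromosome X held 37 peaks, 0.217 per Mb (95% Poisson interval 0.153 to 0.299), which was 0.23 times the density of autosomes (exact binomial test, adjusted p = 6.0e-29). Chromosome Y held 39 peaks, 0.429 per Mb (interval 0.305 to 0.587), 0.46 times the autosomes (same exact test, adjusted p = 4.5e-07). None of the 19 autosomes passed the exact binomial test after adjustment, 5 had an unadjusted p under 0.05, and their densities ran from 0.749 per Mb on chromosome 17 to 1.16 per Mb on chromosome 11.

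**Figure D3:**
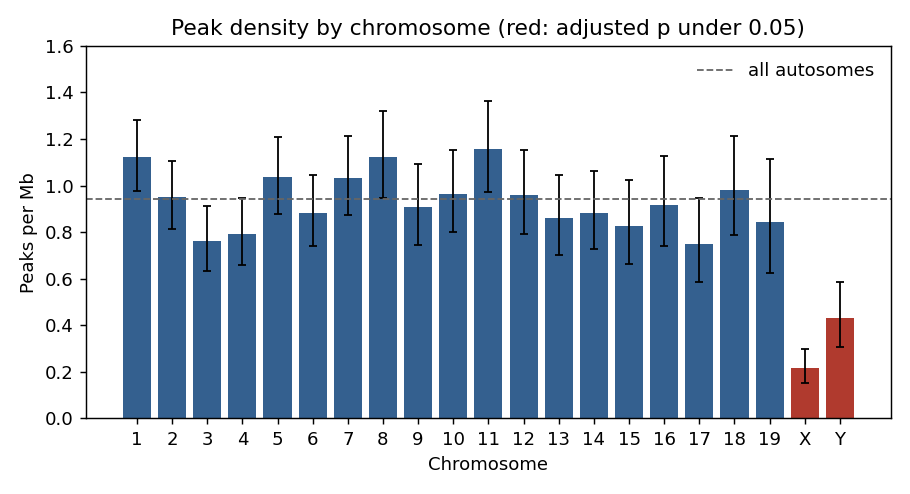
Peaks per Mb on each assembled chromosome, as bars from 0 with 95% Poisson intervals, and the value for all autosomes (0.94 per Mb, dashed). Chromosomes X (0.217) and Y (0.429), in red, are the 2 that passed the adjusted exact binomial test.

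Peak width did not separate peaks near gene ends from other peaks. Many widths lay close to the minimum of 215 bp (25th percentile 228 bp), so this measure had little range to show a difference. Whether width follows peak height was not tested. The median width was 252 bp for the 58 peaks within 1 kb of a gene end and 249 bp for the 2319 others (permutation test with 100000 resamples, two-sided p = 0.719). The widest peak, 743 bp at 27014916 to 27015658 on chromosome 7, lay 13803 bp from Cyp2a12, a cytochrome P450 gene, and the next widest, 659 bp at 113746989 to 113747647 on chromosome 3, lay 117169 bp from Rnpc3. Both were chosen after their widths were seen.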

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

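Outside the comparisons above, 14 peaks fell on 10 unplaced sequences of the assembly. JH584304.1 held 3 of them, and GL456210.1 and GL456221.1 held 2 each. Lengths and genes of these sequences were not used here, so no expected number was computed and the count is given as a value alone.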

How the results depend on the processing

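Some of the alternatives below, those on wider peaks, on width as a measure in place of score (its 3 kb distance was planned), distances of 100 bp and 10 kb, shifted lists, chromosome sets, dense windows, gene biotypes, nearest genes, gene bodies and placement tests of gene lists, were chosen after the data were seen. The number of peaks was 2377 on assembled chromosomes and 2390 after merging peaks within 500 bp, and keeping only peaks wider than the median left 1179, by construction. The ratio of peaks at gene ends to random placement stayed below 1 in each alternative run, from 0.69 without chromosome 16, which was left out for its excess, to 0.91 within 10 kb, with one-sided p for more of 0.647 (within 100 bp) or higher. At 1 kb the two-sided permutation test did not call fewer peaks than at random for protein-coding ends (permutation p = 0.096). For the ends of genes of every biotype, the same two-sided permutation test called fewer (113 against 148, permutation p = 0.006). Without chromosome 16 no call was drawn from the permutation test, because leaving that chromosome out for its excess favours fewer peaks by construction. The number of called gene lists stayed at 0 in 6 of 7 alternatives and became 1 with nearest-gene assignment and Fisher's test (stem cells and Wnt signalling), where the placement test gave 0. The difference in median width was 3 bp within 1 kb of a gene end and turned to -2 bp within 3 kb (permutation p = 0.719 and 0.801); the cause was not tested. No paired analysis was possible because the list has no column for a single library, and for the same reason no replicate could be left out. Not run were the alternatives that need a peak score, the authors' annotation class or the ETS motif. Depth is unknown, and with 2377 peaks an excess at gene ends of 1% of peaks was called in 69% of simulated lists. Those lists started from random placement. The deposited list lay below random near gene ends (ratio 0.77 within 3 kb), so an equal addition to it could be called less often.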

Other observations

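All tests in this part were chosen after the positions of the peaks were seen. The genes with 3 or more peaks inside them were mostly long, with a median length of 1069 kb. Cdh13, a cadherin gene of 1185 kb on chromosome 8, held 6 peaks against 1.33 expected from its length. Tenm4 (teneurin) on chromosome 7, Gpc6 (glypican) on chromosome 14, Kcnip4 on chromosome 5 and Fhit on chromosome 14 held 4 each. Gm7592 on chromosome 1, much shorter at 229 kb, also held 4, against 0.257 expected from its length. It lies in the densest 1 Mb window given below. Another 22 genes, including Ephb1, an ephrin receptor gene, Dscam, Nrg1, Nrxn3 and Cntnap2, held 3. No single gene passed adjustment over 21883 genes (one-sided Poisson test, 0 genes, 42 genes with 2 or more peaks at an unadjusted p under 0.05). As a group, 28 genes held 3 or more peaks against a mean of 15.9 in random placements (permutation of positions, one-sided p = 0.006). The median length was 147.5 kb for genes with a peak and 16.2 kb for genes without one.

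Peaks also clustered in space. Neighbouring midpoints lay less than 5 kb apart in 24 pairs against 10.99 at random (permutation of positions, one-sided p = 0.002) and less than 100 kb apart in 241 pairs against 211 (p = 0.022). Of the 2714 windows of 1 Mb, 6 held 6 or more peaks, against a mean of 1.17 and a maximum of 5 such windows in random lists. The densest, from 85000001 to 86000000 on chromosome 1, held 8 peaks and includes Sp100, Sp110, Sp140 and a set of predicted genes. Windows on chromosome 5 (from 15000001, with Speer4c and Speer4d), chromosome 9 (from 3000001) and chromosome 8 (from 20000001, with Defb33) held 7, 7 and 6 peaks, and those on chromosome 7 (from 27000001, with Cyp2a12 and several zinc finger genes) and chromosome 10 (from 50000001) held 6 each. Even placement along the chromosome spans is argued against by the one-sided permutation p of 0.000999, the smallest that 1000 placements can give. Those spans include assembly gaps, where no peak can lie, so the random lists are somewhat too spread out. Chance placement over the sequence where peaks could be called was not tested. A candidate explanation, reads shared between near-identical copies of gene families, stays open. With placeholder names left out, 40% of genes on average shared the letters of their symbol with another gene of the window in the 4 of these windows with 3 or more such genes, against 18.2% in 1686 other windows, which missed the threshold (permutation test, one-sided p = 0.076). Pseudogenes averaged 7.33 over the 6 windows against 3.83 in the others (permutation test, one-sided p = 0.033), and mappability was not measured. No biological explanation was tested, because the design has 1 condition.

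For the absence of an excess at gene ends, the tables argue against 1 technical explanation. Coordinates of another genome build would displace genes from peaks, but the list ends beyond the GRCm39 chromosomes on 3 chromosomes, and the gene table is of GRCm38. The pooling of 5′ and 3′ ends stays open: the ratio for either end was 0.81, but random placement gives 36.0 peaks at 1 end per gene, and how the 58 divide between 5′ and 3′ ends is unknown. A list made largely of background positions, and a loss of reads in GC-rich regions, also stay open, since the list has no scores and no sequence was used here. No biological explanation was tested.

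The low density on chromosome X, 0.23 times that of autosomes (95% interval 0.162 to 0.317), may reflect a single copy of that chromosome in male animals, but the labels do not give the sex. In that case a density proportional to copy number would be 0.5, above the interval, although a peak threshold need not respond in proportion. Chromosome Y, also present once in males, had 1.98 times the density of X (exact binomial test, p = 0.004), and its repeated sequence could add peaks. Copy number and mappability therefore cannot be told apart here.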
